A study of Aspergillus oryzae RIB40 with 7 samples.

How the data were processed

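Total RNA from mycelia of the manR disruptant (4 arrays), the manR overexpressor (3 arrays) and a control strain was compared on Agilent arrays with 2 dyes and 43647 spots each. Per the labels, conidia were grown for 18 h at 30 °C, moved to medium with 1% konjac glucomannan for 6 h, and 500 ng of RNA was labelled per sample. The design text states 4 and 3 biological replications. The labels do not say whether the control RNA was shared between arrays.

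Per the file headers, Agilent Feature Extraction 9.5.1 measured each spot's mean signal and its local background as an intensity in both dyes and set the flags for spots well above background, saturated or uneven. The same deposited files give a log10 ratio of red over green after the scanner software's background subtraction and dye normalization. The series table deposited by the authors holds 1 log2 ratio per spot and array, with the dye swaps already turned to mutant over control. Against log2 of the scanner software's turned ratio its slopes were 0.997 to 1.00 and its correlations 0.964 to 0.995. Its medians on the arrays were 0.02, 0.05, 0.03 and 0.07 for the disruptant and −0.00, 0.00 and 0.11 for the overexpressor. How that table was centred or normalized beyond the scanner software is not stated.

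The ratios were computed from the mean signals and local backgrounds with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, and the dyes were normalized within each array by loess. Control spots were left out after normexp and had a weight of 0 in loess, and spots marked as uneven or as population outliers were left out. The 2 spots of a probe were averaged. A gene was tested when it was well above background in the mutant channel or in the control channel on at least 3 arrays of 1 comparison, which held for 10673 of 12107 genes and left out 1434. Of the 12107 identifiers, 12009 matched a locus tag of the RefSeq table, 714 of them with a symbol, and 98 matched none. The RefSeq table served only for symbols and for the order of neighbouring genes. The array's genome build is not named, and no coordinates are given.

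One linear model per gene was fitted to all 7 arrays, with a term for each mutant against the control and a term for the dye, followed by empirical Bayes moderation (prior degrees of freedom 2.49, total 6.49). Genes were called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and all tests were two-sided. The third comparison was the overexpressor term minus the disruptant term. A gene counted in both mutants when both terms passed, beside the count that independent calls would give. Arrays of the same group differed by a median absolute deviation of 0.187 to 0.508 in log2 ratio, and both spots of a probe on an array by 0.0361 to 0.0427. The precision of a single ratio is thus set by the arrays and not by the spots. The SE printed with a ratio comes from the model, with a moderated spread shared by all 7 arrays. The n beside it counts the arrays of that mutant. Disruptant arrays differed by 0.228 to 0.508 and overexpressor arrays by 0.187 to 0.243, so such an SE can understate the scatter between disruptant arrays. Both dyes gave signals well over background on every array, with the lowest median ratio of signal to background, 5.89, in Cy3.

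Groups, tests, gene lists, named genes and alternatives were chosen before the data were examined, with 1 exception. Of the planned lists, 16 rested on annotation text that neither the files nor the RefSeq table holds, so they could not be tested. A list of 13 recalled polysaccharide-degradation loci, the kojic acid cluster (3 loci) and the aflatoxin cluster (27 loci, 11 tested) remained. The exception is a set of 14 lists of RefSeq gene symbols, written after the files had been seen and before any model was fitted. They were plant cell wall-degrading enzymes, fungal cell wall enzymes, ergosterol synthesis, proteasome, ribosome biogenesis, secretory pathway, heat shock proteins, oxidative stress enzymes, iron and siderophore genes, zinc transporters, peroxisome, conidiation regulators, central carbon metabolism and amino acid synthesis. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, and the p were adjusted separately over the 3 planned and over the 14 added lists. Camera with an estimated correlation and fry were run as alternatives. Camera compares a list with the other tested genes, while fry tests its members against no change, so a p by fry answers a different question.

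Genes were named by a rule. It took a recalled manR locus, the 10 largest rises and 10 largest falls among called genes with the same direction on every array of a comparison, and up to 4 called members of each list (up to 2 of the largest where none was called). It also took the 10 genes most strongly lower in the disruptant and higher in the overexpressor, and 5 for each other pair of directions. The text prints part of them, with preference for genes whose call held under the alternatives, and a gene outside the rule is marked as chosen after its values were seen. No ratio is given for a named gene in a strain whose channel was well above background on 0 arrays, though the list tests use such ratios.

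Alternatives of processing were no background subtraction, median centring, no filter on dim probes and scaling of the ratios to a common spread. The scanner software's log ratios and the series table were also used in place of the computed ratios. Alternatives of the model were no dye term, each comparison on its own arrays and a replicate block with the dye term. With that block the mutant terms describe replicate 1. A minimum of 2-fold and each array left out in turn completed the alternatives.

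The model was tested on simulated data with 10673 genes, of which 50 were changed at each size. For the disruptant design it recovered 74% of changes of 1 and 100% of changes of 2 on the log2 scale, with 7 false calls. For the overexpressor design it recovered 58% and 92%, with 3 false calls. Camera gave a p under 0.05 for 2 of 100 random lists of 15 genes, and it called the list raised by construction. Far fewer genes were changed than were called in the data, and the adjusted p depends on that share. The recovery rates and false calls therefore need not carry over. The normalization was not simulated. The simulated noise was independent between genes. These counts therefore do not measure false calls where genes move together, as in ribosome biogenesis, with an estimated correlation of 0.947.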

Results

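Transcript levels were measured in mycelia of Aspergillus oryzae, the mould used to ferment soy sauce and rice wine, on 7 Agilent dual-colour arrays. Each array held the RNA of a mutant strain and the RNA of a control strain, labelled with Cy3 and Cy5. The manR disruptant was measured on 4 arrays and the manR overexpressor on 3, which the design text calls biological replicates. The control strain descends from the reference strain RIB40 and, per the labels, lacks ku70, a gene of DNA end joining, and the aflatoxin gene cluster. All cultures had grown for 6 h at 30 °C on 1% konjac glucomannan, a plant polysaccharide of linked mannose and glucose, as the sole carbon source. Mutant RNA carried Cy5 on disruptant replicates 1 and 3 and on overexpressor replicates 1 and 2, and Cy3 on the others. Between 9544 and 11085 of 12107 genes were well above background in the mutant channel of an array, and between 10150 and 10953 in the control channel. The median spot signal was 5.89 to 11.4 times the local background in Cy3 and 13.5 to 21.6 times in Cy5, and 0 gene spots were saturated. The number of arrays limits the precision, with a median SE of 0.13 on the log2 scale for the disruptant and 0.16 for the overexpressor.

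No gene is named manR in the files or in the RefSeq table, so the level of the targeted transcript could not be read. AO090011000944, recalled as a possible manR locus, fell by 0.56 ± 0.12 on the log2 scale in the disruptant (SE, n = 4) and by 0.71 ± 0.14 in the overexpressor (n = 3), with limma adjusted p = 0.0174 and 0.00445. It is therefore not named manR here. Its call in the disruptant was lost without disruptant replicate 2 (adjusted p = 0.0741) or replicate 4 (0.0567).

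The first comparison asks which transcripts differed between the manR disruptant and the control during growth on glucomannan. manF, which encodes a mannanase that cuts mannan chains, fell 7.73-fold in the disruptant (log2 −2.95 ± 0.41, SE, n = 4), and AO090038000445, its neighbour in the RefSeq order, fell 23.1-fold (log2 −4.53 ± 0.35). AO090010000208 fell 12.5-fold (log2 −3.64 ± 0.12) and AO090010000122 fell 11.1-fold (log2 −3.47 ± 0.18), both loci recalled for plant polysaccharide breakdown. cbhC, which encodes a cellobiohydrolase that cuts cellulose, fell 2.46-fold (log2 −1.30 ± 0.15). Among the 10 largest falls were also AO090005000740 (log2 −4.67 ± 0.12), AO090003000497 (−4.27 ± 0.14), AB227738 (−4.14 ± 0.11), AO090003001305 (−4.08 ± 0.16) and AO090020000141 (−3.96 ± 0.20). The largest rises were those of AO090103000479 (log2 3.58 ± 0.29), AO090020000639 (3.49 ± 0.34) and AO090003000798 (3.35 ± 0.32). AO090001000571 (3.08 ± 0.49) and AO090009000275 (2.98 ± 0.41) were also among the 10 largest rises. Without disruptant replicate 1 the ratio of AO090001000571 was 3.81. With the scanner's log ratios that of AO090020000639 was 4.80 and that of cbhC −1.95. Several of these genes moved the same way in the overexpressor. Fitted without the dye term, AO090005000740, AB227738, AO090003001305 and AO090020000141 had −1.42, −1.32, −1.99 and −1.05 there. Under median centring AB227738 and AO090020000141 had 0.03 and 0.18. Without the dye term AO090103000479, AO090003000798 and AO090001000571 had 3.88, 3.87 and 3.63. By contrast AO090003000497 then had 0.67 and AO090020000639 −0.10.

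In total, 3105 of 10673 tested genes changed in the disruptant (29.1%, limma, adjusted p under 0.05), of which 1486 rose and 1619 fell (1068 and 1667 under median centring). Of the 3105, 440 rose and 498 fell by at least 2-fold. Of the 1619 that fell, 1353 were also called lower in the overexpressor, and of the 1486 that rose, 931 were also called higher there. A change in the disruptant alone therefore does not show dependence on manR. The count was 1524 when the disruptant arrays were fitted on their own, 1476 without replicate 2, 1825 without replicate 3 and 1925 without replicate 4. Scaling the ratios to a common spread enlarges those of arrays with a small spread by construction. Most disruptant ratios of named genes were then larger, for example −5.93 for AO090038000445 and −4.58 for AO090010000122. Replicate 1 stood apart: its ratios correlated with those of the other disruptant arrays at r between 0.302 and 0.467 across genes, which are not independent replicates.

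Of the 13 recalled polysaccharide-degradation loci, 5 fell in the disruptant, 1 rose and 7 did not pass the test. Adjusted over the list alone, 6 fell and 1 rose. The 5 that fell were AO090010000208, AO090010000122, manF, cbhC and AO090001000348 (log2 −1.30 ± 0.20, n = 4). The list shifted down by camera (adjusted p = 0.0160, and adjusted p = 0.202 with an estimated correlation), and the call was lost under median centring (adjusted p = 0.104, in a range of 0.00496 to 0.104 for camera at the preset correlation over the alternatives). The test by fry gave 0.000316. These loci were recalled from literature that includes work on manR, so the list is not independent evidence of its direction. In the list of plant cell wall-degrading enzymes chosen by gene symbol, 6 of 15 fell and 0 rose (adjusted p = 0.0591). They included manF, cbhC, bxlB, a xylosidase gene (log2 −0.83 ± 0.13), and aglA, an alpha-galactosidase gene (−2.80 ± 0.53), whose call was lost on the disruptant arrays alone (adjusted p = 0.0526). The ratio of aglA was −3.39 without disruptant replicate 3 and −2.13 without replicate 4, and that of bxlB was −1.42 with the scanner's log ratios. This list passed without disruptant replicate 1 (adjusted p = 0.0336), disruptant replicate 4 (0.0226) or overexpressor replicate 3 (0.0365), and on the disruptant arrays alone (0.0370), with a range of 0.0226 to 0.158 for camera at the preset correlation over the alternatives. It had an adjusted p of 0.701 with an estimated correlation and 0.00903 by fry. Under every alternative but the replicate block and the 2-fold minimum, 5 of the 5 falls held in the recalled list and 3 of the 6 in the list by symbol.

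Iron and siderophore genes, which serve iron uptake, shifted up in the disruptant: 8 of 13 rose and 0 fell (camera adjusted p = 0.00892, and adjusted p = 0.701 with an estimated correlation). sit2, a siderophore transporter gene, rose by log2 1.94 ± 0.35 (SE, n = 4), sidJ by 1.69 ± 0.27, fetC by 1.31 ± 0.20 and mirD by 1.27 ± 0.24. The call for mirD was lost without disruptant replicate 3 (adjusted p = 0.0520), and its ratio was 2.10 with the scanner's log ratios. For sit2 the ratio was 0.09 on replicate 1 and 2.18 to 3.01 on the others. Amino acid synthesis genes shifted up, with 9 of 17 rising and 2 falling (adjusted p = 0.00823, and adjusted p = 0.718 with an estimated correlation), and the call was lost without disruptant replicate 3 (adjusted p = 0.0561), with the replicate block (0.807) and by fry (0.0853). For camera at the preset correlation the range over the alternatives was 8.1e-05 to 0.807. Of these genes, met16, of sulfate assimilation, rose by log2 2.19 ± 0.42 and met2 by 1.18 ± 0.16. The call for met16 was lost without disruptant replicate 2, 3 or 4 (adjusted p = 0.0618, 0.0576 and 0.0539), and its ratio was 2.83 without replicate 1. Heat shock proteins shifted up, with 4 of 9 rising and 0 falling (adjusted p = 0.00823, and adjusted p = 0.718 with an estimated correlation). The call for this list was lost with the replicate block (0.585) and by fry (0.0765). The rising members were hsp70 (log2 0.98 ± 0.25), hsp88 (0.96 ± 0.22), fes1 (0.87 ± 0.18) and wos2 (0.54 ± 0.12). The calls for all 4 were lost without disruptant replicate 2 (adjusted p between 0.0549 and 0.121) or replicate 3 (0.0566 to 0.0837), and for all but fes1 without replicate 4 (0.0653 to 0.106). The call for hsp70 was also lost with the scanner's log ratios (0.0662), with the series table (0.0647) and without overexpressor replicate 2 (0.0507), and that for wos2 under median centring (0.0576). The calls that held under every alternative but the replicate block and the 2-fold minimum were 4 of the 8 rises in the iron list, 1 of 9 in amino acid synthesis and 0 of 4 in heat shock proteins.

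The remaining lists did not pass the camera test in the disruptant. In central carbon metabolism 7 of 16 genes rose and 0 fell (adjusted p = 0.0591), among them kgd1, of the citric acid cycle (log2 0.79 ± 0.15, n = 4), and pgkA, of glycolysis (1.88 ± 0.35), whose call was lost without disruptant replicate 2 (adjusted p = 0.0558) or 3 (0.0505). Ribosome biogenesis had 0 of 28 changed genes (0.128) and the proteasome 0 of 15 (0.675). The ergosterol list had 3 rising and 1 falling of 18 (0.553), with erg4A at log2 0.73 ± 0.09 and idi1 at −0.88 ± 0.14. Without disruptant replicate 1, ribosome biogenesis (adjusted p = 9.4e-05), ergosterol synthesis (0.0292) and central carbon metabolism (0.0227) shifted up. Without disruptant replicate 4, ribosome biogenesis (0.0119) and central carbon metabolism (0.0226) did. The central carbon list also passed without overexpressor replicate 3 (0.0365), on the disruptant arrays alone (0.0370) and under median centring (0.0114). For camera at the preset correlation the adjusted p over the alternatives ranged from 9.4e-05 to 0.959 for ribosome biogenesis, 0.0292 to 0.959 for ergosterol synthesis and 0.0114 to 0.148 for central carbon metabolism. With an estimated correlation it was 0.888 for ribosome biogenesis, 0.888 for ergosterol synthesis and 0.718 for central carbon metabolism, and none of these passed by fry (0.588, 0.536 and 0.0765). The secretory pathway had 5 rising and 2 falling of 22 (0.211), with sec23 at 0.75 ± 0.10. Fungal cell wall enzymes had 5 rising and 4 falling of 27 (0.978), with the alpha-glucan synthase gene ags1 at 1.55 ± 0.27. Oxidative stress enzymes had 1 of 8 rising, trr1 at 1.82 ± 0.28, and 1 falling (0.638). Of 3 zinc transporters 2 passed upward (0.128), with zrfD at 1.64 ± 0.18. The call for the other, zrfB, was lost under most alternatives, among them no dye term (adjusted p = 0.104), the disruptant arrays alone (0.0665) and any 1 disruptant array left out (0.0658 to 0.168). Of 18 peroxisome genes 2 passed upward, pex13 and pex20 (0.333), and adjusted over the list alone 0 did. The calls of both were lost with any 1 array left out, under median centring (adjusted p = 0.111 and 0.218) and on the disruptant arrays alone (0.155 and 0.132). Of 13 conidiation regulators 1 rose and 3 fell (0.128), with flbD at −0.53 ± 0.09. In the kojic acid cluster 1 of 3 loci rose, and adjusted over the list alone 2 rose (0.0789). The call for AO090113000137, the 1 that rose, was lost under median centring (adjusted p = 0.0963), without the dye term (0.0596), on the disruptant arrays alone (0.0688) and without disruptant replicate 2, 3 or 4 (0.0640, 0.0791 and 0.0662). This cluster passed with the scanner's log ratios (adjusted p = 0.0292) and with the series table (0.0343), in a range of 0.0292 to 0.416 for camera at the preset correlation. It also passed by fry (0.0125), but not with an estimated correlation (0.362). Of the 27 loci of the aflatoxin cluster 11 were tested, and 1 of them fell, also adjusted over the list alone (0.834). Their median was 0.02, with a mean of −0.08 and a camera direction of down. Of the 11, 7 had a mean log2 intensity under 7, so the list rests mostly on loci near background. Of the rises counted in this paragraph, those that held under every alternative but the replicate block and the 2-fold minimum were 1 of 7 in central carbon metabolism, 1 of 3 in ergosterol synthesis, 2 of 5 in the secretory pathway and 2 of 5 in fungal cell wall enzymes. Of the falls, 0 of 4 held in fungal cell wall enzymes, 0 of 2 in the secretory pathway, 0 of 1 in oxidative stress enzymes and 1 of 3 in conidiation regulators, where the 1 rise did not hold.

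The second comparison asks which transcripts changed in the manR overexpressor, where the level of manR itself could not be read. In the overexpressor, AO090010000122 rose 6.47-fold (log2 2.69 ± 0.21, SE, n = 3), cbhC 5.04-fold (2.33 ± 0.18) and manF 4.60-fold (2.20 ± 0.48). The endoglucanase gene eglD rose 11.7-fold (3.54 ± 0.13), and the xyloglucanase gene xgeA rose 5.23-fold (2.39 ± 0.11). AO090038000445, next to manF, rose 9.71-fold (3.28 ± 0.41). By contrast the alpha-galactosidase gene aglA fell 36.1-fold (−5.18 ± 0.63). The largest falls were those of AO090038000471 (−6.06 ± 0.20), AO090020000504 (−6.02 ± 0.34), AO090023000804 (−5.98 ± 0.77) and AO090103000145 (−5.90 ± 0.42). The largest rises were those of AO090038000465 (5.79 ± 0.77), AO090701000330 (5.22 ± 0.22), AO090701000327 (4.68 ± 0.14) and AO090011000152 (4.61 ± 0.69). Without overexpressor replicate 3 the ratios were 3.48 for manF, 4.25 for AO090038000445, −6.82 for AO090023000804 and −6.65 for AO090103000145. They were then 7.50 for AO090038000465 and 5.90 for AO090011000152, against 5.74 for AO090701000330 and 4.97 for AO090701000327, so the order of the largest changes depends on that array. It depends on the centring too: under median centring AO090038000471 had −4.68, AO090020000504 −5.58, AO090023000804 −5.29, AO090103000145 −5.75 and aglA −4.51. The ratios were then 6.69 for AO090038000465, 3.77 for AO090010000122, 3.67 for manF and 4.56 for AO090038000445. With the scanner's log ratios AO090701000327 had 5.49. No disruptant ratio is given for eglD, AO090701000330 and AO090701000327, which were well above background on 0 arrays in the disruptant channel.

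In total, 6843 of the 10673 genes changed in the overexpressor (64.1%, limma, adjusted p under 0.05), of which 3241 rose and 3602 fell (3336 and 3326 under median centring). Of the 6843, 1692 rose and 2066 fell by at least 2-fold. With the ratios scaled to a common spread on all arrays the count was 4411, and the call for manF was lost (log2 1.69, adjusted p = 0.0572). This scaling shrinks the ratios of arrays with a wide spread by construction. Most overexpressor ratios of named genes were smaller with it, for example 2.49 for eglD and 4.17 for AO090038000465.

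Of the recalled polysaccharide-degradation loci, 7 of 13 rose and 1 fell in the overexpressor, and the same counts were found adjusted over the list alone. The camera test did not pass (adjusted p = 0.0657), except without overexpressor replicate 3 (0.0345), in a range of 0.0345 to 0.0999 for camera at the preset correlation over the alternatives. With an estimated correlation the adjusted p was 0.328, and by fry 0.000824. The locus that fell was AO090009000356 (log2 −4.77 ± 0.24, n = 3, and −3.82 under median centring), against rises of AO090010000122, cbhC, AO090012000941 (2.22 ± 0.15, and 3.81 with the scanner's log ratios) and manF. Of the plant cell wall-degrading enzymes chosen by symbol, 6 of 15 rose and 3 fell (0.424, and 0.00128 by fry), with eglD and xgeA among the former and aglA among the latter. Under every alternative but the replicate block and the 2-fold minimum, 5 of the 7 rises held in the recalled list, and 3 of the 6 rises and 2 of the 3 falls in the list by symbol.

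Genes of ribosome biogenesis rose together in the overexpressor: all 28 rose (camera adjusted p = 1.0e-06, and adjusted p = 0.737 with an estimated correlation). nop7 rose by log2 2.64 ± 0.58 (SE, n = 3), dbp3 by 2.54 ± 0.55, rrp3 by 2.18 ± 0.37 and loc1 by 2.18 ± 0.40. With the ratios scaled to a common spread, the calls for these 4 genes were lost (adjusted p between 0.0549 and 0.116). Of the amino acid synthesis genes 13 of 17 rose and 3 fell (adjusted p = 0.00644, and adjusted p = 0.737 with an estimated correlation), with the largest rises in met16 (3.26 ± 0.50), ilv3 (2.03 ± 0.38) and met2 (1.92 ± 0.19). The call for ilv3 was lost with a common spread (adjusted p = 0.0613). Iron and siderophore genes shifted up, with 10 of 13 rising and 1 falling (adjusted p = 0.00644, and adjusted p = 0.737 with an estimated correlation). Here sidJ rose by 3.89 ± 0.31, sit2 by 3.77 ± 0.42, mirB by 3.27 ± 0.16 and mirD by 3.08 ± 0.28. With the scanner's log ratios sidJ had 4.52 and mirD 3.93. The iron and amino acid synthesis lists shifted up in the disruptant as well, so their rise is not particular to either mutant. Ergosterol synthesis shifted up, with 14 of 18 rising and 2 falling (adjusted p = 0.0163, and adjusted p = 0.737 with an estimated correlation). The squalene epoxidase gene erg1 rose by 3.22 ± 0.45, while idi1, of isoprenoid synthesis, fell by 2.63 ± 0.16, and by 1.53 under median centring. Without overexpressor replicate 3 the ratio was 3.98 for erg1 and 4.21 for met16. The secretory pathway shifted up, with 11 of 22 rising and 2 falling (adjusted p = 0.0395, and adjusted p = 0.737 with an estimated correlation). Its members alg3 and alg10, of glycan assembly, rose by 1.35 ± 0.16 and 1.35 ± 0.15. The call for this list was lost without overexpressor replicate 2 (adjusted p = 0.102), without the dye term (0.0556) and with the replicate block (0.183), in a range of 0.000826 to 0.183 for camera at the preset correlation. The call for ergosterol synthesis was lost with the replicate block (0.0728). The rises that held under every alternative but the replicate block and the 2-fold minimum were 6 of 28 in ribosome biogenesis, 9 of 13 in amino acid synthesis, 8 of 10 in the iron list, 4 of 14 in ergosterol synthesis and 4 of 11 in the secretory pathway.

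Several other groups held genes that moved both ways in the overexpressor, while heat shock proteins, zinc transporters and the kojic acid cluster held no called falls. In central carbon metabolism 8 of 16 rose and 6 fell (camera adjusted p = 0.759), with pgkA at log2 2.20 ± 0.41 (n = 3), the trehalase gene treA at −3.71 ± 0.23 and acuF, of gluconeogenesis, at −1.94 ± 0.24. The median of this list was 0.62 and its mean 0.06, and camera gave up where fry gave down. Fungal cell wall enzymes had 3 rising and 13 falling of 27 (0.117), with ags1 at 2.79 ± 0.32 and the glucan transferase gene gel1 at −1.75 ± 0.27. Of 13 conidiation regulators 7 fell and 1 rose (0.154), with esdC at −3.55 ± 0.47, veA at −1.83 ± 0.19 and flbA at 1.64 ± 0.23. Of 18 peroxisome genes 7 fell and 3 rose (0.457), with farB1, a regulator of fatty acid use, at −1.89 ± 0.17 and pxa1 at −1.78 ± 0.22. Of 8 oxidative stress enzymes 4 fell and 2 rose (0.457), with cat1 at −2.72 ± 0.24 and trr1 at 2.47 ± 0.34. Without overexpressor replicate 3 the ratio was 3.09 for pgkA, 3.42 for ags1 and 3.07 for trr1. Under median centring it was 3.45 for pgkA, −3.08 for treA, −2.65 for esdC and −1.85 for cat1. The camera direction of the oxidative list was up under median centring (0.723). Of 9 heat shock proteins 3 rose and 0 fell (0.424), and the list passed under median centring (0.0155) and without overexpressor replicate 3 (0.0453), in a range of 0.0155 to 0.773 for camera at the preset correlation (0.868 with an estimated correlation and 0.284 by fry). Of 15 proteasome genes 1 rose and 2 fell (0.457), with pre1 at −0.66 ± 0.13 and pre4 at −0.65 ± 0.12, whose ratios were 0.27 and 0.30 under median centring, where the list shifted up (0.0113, in a range of 0.0113 to 0.971 for camera at the preset correlation, with 0.868 with an estimated correlation and 0.313 by fry). The call for pre1 was also lost with a common spread (0.0684). Of 3 zinc transporters 1 passed upward, zrfD (0.612), and its call was lost without overexpressor replicate 1 (0.0737) or 2 (0.108) and with a common spread (0.144). In the kojic acid cluster all 3 loci passed upward, also adjusted over the list alone (0.0885), with AO090113000137 at 1.18 ± 0.13. The call for AO090113000136 was lost under median centring (0.0839). That for AO090113000138 was lost on the overexpressor arrays alone (0.0534), with a common spread (0.186), without disruptant replicate 2 or 3 (0.0595 and 0.0620) and without overexpressor replicate 1, 2 or 3 (0.150, 0.160 and 0.0766). Of the 11 tested aflatoxin loci 1 rose and 3 fell, with the same counts adjusted over the list alone (0.904). Their median was 0.06, with a mean of −0.36 and a camera direction of down, and the 7 loci near background limit this list here too. By fry the lists of fungal cell wall enzymes (0.0266), conidiation regulators (0.0273), oxidative stress enzymes (0.00304) and the kojic acid cluster (0.00199) passed. Of the falls counted in this paragraph, those that held under every alternative but the replicate block and the 2-fold minimum were 8 of 13 in fungal cell wall enzymes, 4 of 7 in conidiation regulators, 2 of 7 in peroxisome genes, 3 of 6 in central carbon metabolism and 2 of 4 in oxidative stress enzymes. Of the rises, 4 of 8 held in central carbon metabolism, 2 of 3 in fungal cell wall enzymes, 1 of 3 in peroxisome genes, 1 of 2 in oxidative stress enzymes and 0 of 3 in heat shock proteins. In the proteasome list 0 of the 3 calls held.

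**Figure D1:**
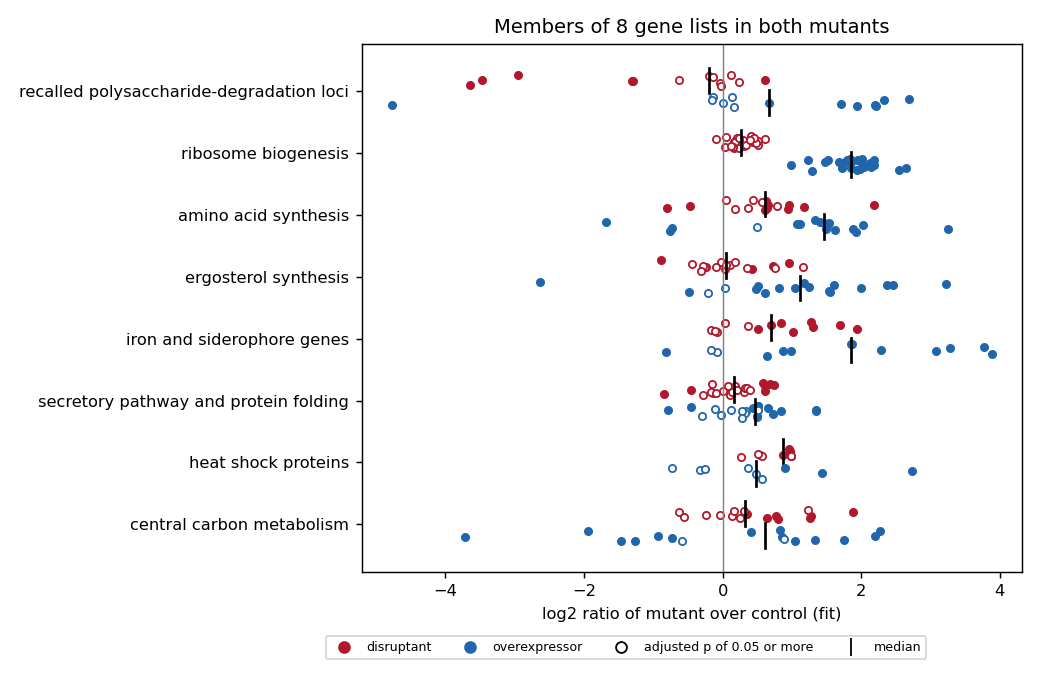
Fitted log2 ratios of mutant over control (horizontal axis) for the members of 8 gene lists, in the disruptant (red) and the overexpressor (blue), with filled points where the limma adjusted p was under 0.05 and a black line at the median of each list. All 28 ribosome biogenesis genes lay above 0 in the overexpressor with a median of 1.86, against a median of 0.27 and 0 changed genes in the disruptant.

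The third comparison asks which genes responded differently to disruption and overexpression. Genes that fell in the disruptant and rose in the overexpressor numbered 73, where independent calls would give 492. The 10 with the strongest opposite changes were AO090038000445, AO090010000122, XM_003189606.1, AB701764, manF, AO090010000562, AO090005001552, cbhC, AO090001000348 and AO090020000140. XM_003189606.1 had log2 ratios of −2.68 ± 0.26 in the disruptant (SE, n = 4) and 3.50 ± 0.31 in the overexpressor (n = 3). AB701764 had −2.83 ± 0.17 and 2.22 ± 0.21, AO090010000562 had −2.20 ± 0.20 and 3.28 ± 0.24, and AO090020000140 had −1.48 ± 0.18 and 1.26 ± 0.21. AO090005001552 had −1.46 ± 0.15 and 2.24 ± 0.18 but was well above background in the disruptant channel of 2 of the 4 arrays. With the scanner's log ratios the disruptant ratio was −4.25 for XM_003189606.1 and −3.10 for AO090005001552. Under median centring the overexpressor ratio was 3.16 for AB701764 and 3.92 for AO090010000562. Overexpressor replicate 3 gave lower ratios than the mean of replicates 1 and 2 for 7 of these 10 genes, with a median gap of 0.84 and a gap of 3.08 for manF. The count of such genes was 35 with each comparison fitted on its own arrays and 45, 29 and 44 without disruptant replicates 1, 2 and 4. It was 39, 39 and 45 without overexpressor replicates 1, 2 and 3.

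**Figure D2:**
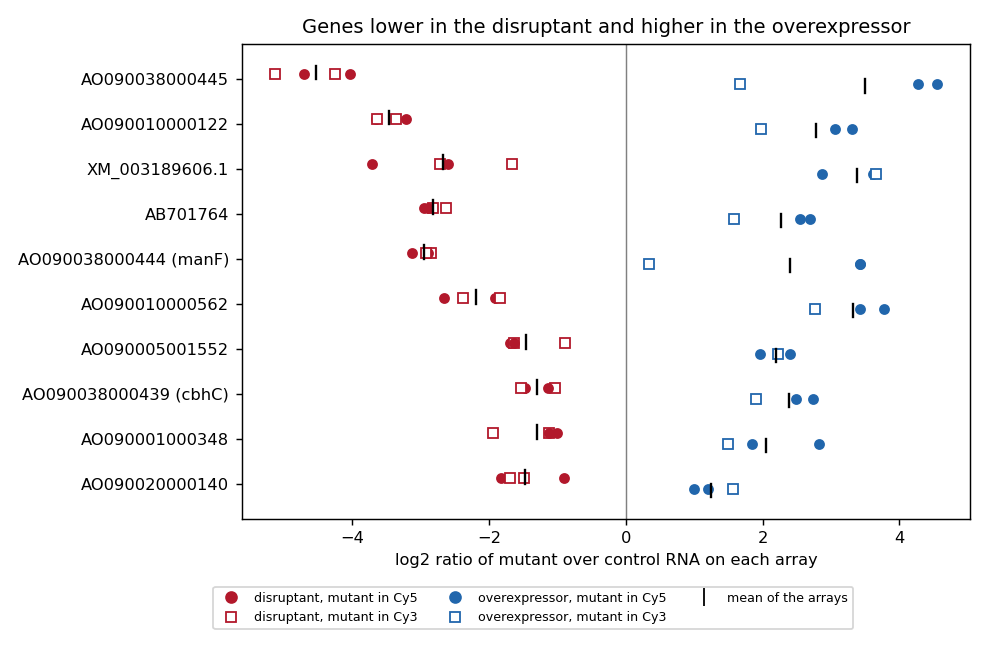
Log2 ratios of mutant over control RNA on each array (horizontal axis) for the 10 genes most strongly lower in the disruptant (red, n = 4) and higher in the overexpressor (blue, n = 3), filled where the mutant RNA carried Cy5 and open where it carried Cy3, with black lines at the means. All disruptant points lie below 0 and all overexpressor points above 0.

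Genes that rose in the disruptant and fell in the overexpressor numbered 126, where independent calls would give 502. AO090011000885 rose by log2 2.09 ± 0.26 in the disruptant (SE, n = 4) and fell by 2.47 ± 0.31 in the overexpressor (n = 3). gliP, named after the peptide synthetase gene of gliotoxin synthesis, rose by 1.88 ± 0.27 and fell by 2.13 ± 0.32, and its neighbour gliG rose by 2.13 ± 0.43 and fell by 1.98 ± 0.50. The calls for gliG were lost in the disruptant on its own arrays (adjusted p = 0.0530) and without disruptant replicate 2 (0.0524). In the overexpressor they were lost without replicate 2 (0.0654) and with a common spread (0.122). The ratio of gliG was 1.47 in the disruptant without disruptant replicate 1, and −3.07 in the overexpressor with the scanner's log ratios. In a run of 34 neighbouring tested genes around gliP, chosen after its values were seen, 24 rose and 2 fell in the disruptant, and 1 rose and 21 fell in the overexpressor.

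**Figure D3:**
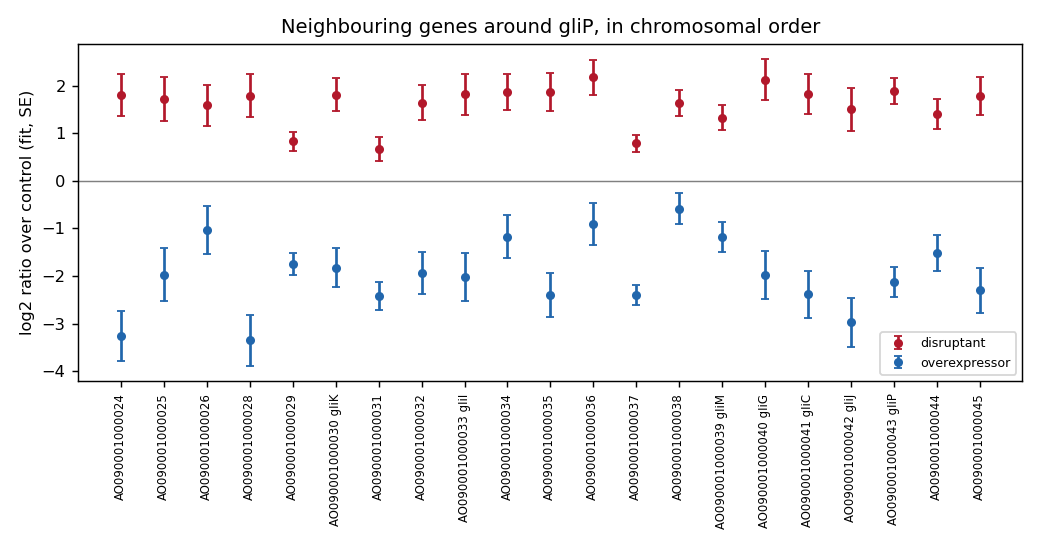
Fitted log2 ratios over control (vertical axis, points with bars of 1 SE) for neighbouring genes around gliP in chromosomal order (horizontal axis), in the disruptant (red) and the overexpressor (blue). The disruptant ratios lie above 0 and the overexpressor ratios below 0, with gliP at 1.88 and −2.13. The genes drawn, AO090001000024 to AO090001000045, are part of the run of 34. In the whole run 2 genes fell in the disruptant and 1 rose in the overexpressor.

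The test of the difference between both responses passed for 4092 genes (38.3%, limma, adjusted p under 0.05), with 1763 higher and 2329 lower in the overexpressor than in the disruptant. Under median centring 2150 were higher and 2126 lower. The count was 890 with the ratios scaled to a common spread, 1786 without overexpressor replicate 1 and 1989 without overexpressor replicate 2. The disruptant arrays came from one slide and the overexpressor arrays from another, so that slide and strain cannot be told apart in this comparison.

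Most genes that changed in both mutants changed in the same direction. Of the genes called in both, 1353 fell in both and 931 rose in both, 92.0% of the total, where independent calls would give 546 and 451. AO090005000743 fell by 4.11 ± 0.13 on the log2 scale in the disruptant (SE, n = 4) and by 3.35 ± 0.16 in the overexpressor (n = 3). AO090038000061 fell by 3.38 ± 0.42 and by 4.49 ± 0.49. AO090103000479 rose by 3.58 ± 0.29 and 3.90 ± 0.35, and AO090003000798 by 3.35 ± 0.32 and 4.01 ± 0.38, with overexpressor ratios of 4.69 and 4.61 without overexpressor replicate 3. Among the genes that changed alike, the difference also passed for 669 of those that fell and 331 of those that rose. Across genes, which are not independent replicates, the fitted ratios of both mutants correlated at r = 0.602 (Spearman 0.593). The ratios of disruptant replicate 1 correlated with the mean overexpressor ratio at 0.0634, and those of replicates 2, 3 and 4 at 0.630, 0.530 and 0.687. Without disruptant replicate 1, 1386 genes fell in both and 1199 rose in both, and r was 0.691.

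**Figure D4:**
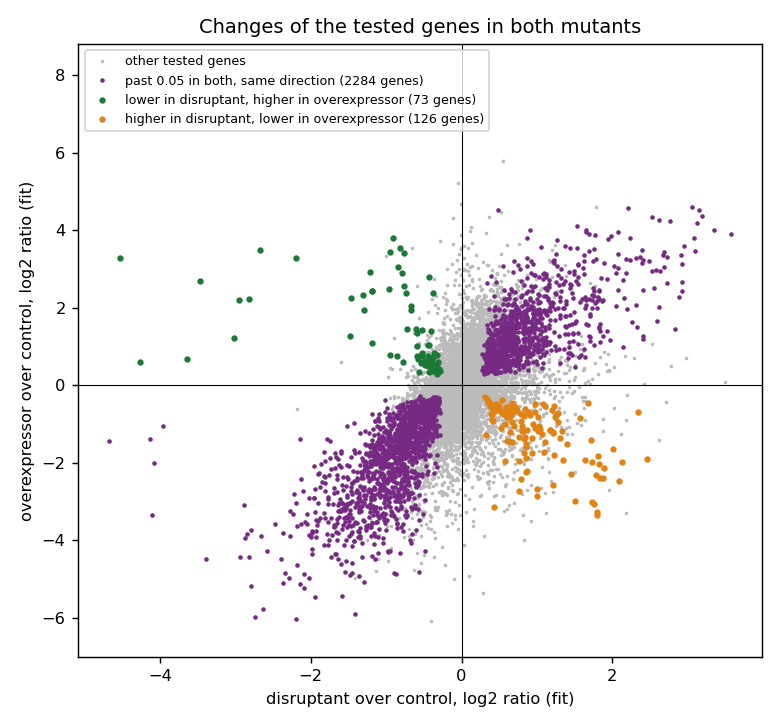
Fitted log2 ratios over control in the disruptant (horizontal axis) and in the overexpressor (vertical axis) for the 10673 tested genes, with colours for genes that passed adjusted p 0.05 in both. The 2284 genes with the same direction spread along the diagonal, and the 73 and 126 genes with opposite directions lie in the other quadrants.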

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

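All tests of explanations in this part, the regroupings of arrays included, were chosen only after the result was seen. Of 89 groups of 4 disruptant values, 5 held 1 array far from the other 3 by Dixon's test, and chance alone gives about 5% of such groups. Most groups were ratios of named genes, and the rest were measures of whole arrays such as genes detected or median signal. AO090026000494 had a log2 ratio of 0.14 on replicate 1 and 3.91 to 4.40 on the others. AO090003000661 had 0.89 on replicate 1 and 3.54 to 3.99 on the others. gliP, AO090001000043, had 3.14 on replicate 1 and 1.37 to 1.65 on the others. AO090005001552 had −0.89 on replicate 4 and −1.69 to −1.63 on the others. AO090001000348 had −1.95 on replicate 4 and −1.12 to −1.01 on the others.

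The disruptant and the overexpressor moved 73 genes in opposite ways, with manF, cbhC and AO090010000122 among those lower in the disruptant. Another 126 genes, with gliP among them, were higher in the disruptant and lower in the overexpressor. The choice of genes called in opposite directions all but fixes the test of their difference, so that test adds nothing for these genes. Of the 35 ways to divide the 7 arrays into groups of 4 and 3, 2 gave at least 73 genes with such a pattern, the true one included, so the share does not exclude chance for that count. The other, with 92, put disruptant replicate 4 and all 3 overexpressor arrays in the place of the disruptant. It keeps 6 of the 7 arrays divided by strain and counts the reverse direction, so it is no clean measure of chance, and the remaining divisions gave at most 1. For the difference between both responses, 1 of 35 divisions gave as many as 4092 genes, the true one, and the highest other count was 1467. A single division is the smallest share that 35 can give. Divisions that mix the strains carry the strain effects in their spread, and slide and strain coincide, so this share is no clean measure of chance. For the 3105 genes changed in the disruptant and the 6843 changed in the overexpressor, turning the signs of single arrays gives 8 and 4 patterns, too few for a share under 0.05, and in each the true pattern was the 1 that reached its count, with a highest other count of 0.

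Some spots that the comparisons do not use gave signal. Spots named Control, Control_B and Control_C, 18015 per array and not typed as controls in the files, were well above background for a median of 77.3%, 89.6% and 17.0% of spots over arrays and dyes. The ranges were 69.3 to 85.6%, 84.6 to 94.4% and 5.31 to 50.1%. Spots typed as negative controls reached at most 7.19%, with a median of 0.654%.

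Many genes changed in the same direction in both mutants. Dye bias is argued against by the correlation of 0.708 across genes between disruptant arrays with mutant RNA in Cy3 and overexpressor arrays with mutant RNA in Cy5, and of 0.227 for the reverse dyes, since a dye effect alone would give negative values. A trend with brightness is argued against by the lowest correlation of both ratios within 10 bins of intensity, 0.445. Control RNA that differed from both mutants for reasons other than manR may have contributed and cannot be told apart from a shared response, since the covariance of both ratios was 0.488 where the design alone gives 0. A response common to both changes of manR stays open and was not tested.

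Disruptant replicate 1 lacked most of the change shared with the overexpressor. Against replicate 3, with the same dyes on the same slide, its control channel differed in a way that correlated across genes with the mean overexpressor ratio at 0.235, and its disruptant channel at −0.265. Different control RNA and different disruptant RNA on that array may each have contributed and cannot be told apart, since both channels moved by a similar amount. No biological explanation was tested.

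Overexpressor replicate 3 gave lower ratios for manF and most of the other genes lower in the disruptant and higher in the overexpressor. Dye bias is argued against by the dye effect on the disruptant arrays, which predicts a median gap of −0.074 where 0.84 was seen, and overexpressor RNA in the control channel at the 76.7% that manF needs is argued against by 1004 genes whose ratio exceeds what that share allows. At the 12.3% that the other genes need at the median, 12 genes exceed it. These other genes need 0% to 28.2% each, while a mixture has 1 share for all genes, so it leaves part of the pattern unexplained. Such a mixture at a low share stays open, as does compression of bright spots, with a slope of 0.808 ± 0.0298 (SE, 105 genes). The control channel was higher than on replicates 1 and 2 by a median of 1.10 for the 10 genes and −0.04 for all tested genes, though the dyes differed. The overexpressor channel moved by a median of 0.25 for the 10 genes. Each gap is the difference between these 2 channel shifts, so the values place it mostly in the control channel without telling its cause. Control RNA with more of these transcripts stays a candidate, but overexpressor RNA in that channel would raise it too. No biological explanation was tested.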

How the results depend on the processing

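All alternatives here were planned except the added symbol lists, whose tests were chosen after the files were seen. Of 185 ratios of named genes, 57 kept direction and call under every alternative. Of 2960 comparisons of such ratios with an alternative, 2612 kept both, 340 lost the call, 3 gained it and 5 turned. Under median centring the overexpressor ratios of pre4 (AO090003000016), pre1 (AO090023000824) and hacA (AO090124000074) became 0.30, 0.27 and 0.53. With the replicate block, where the mutant terms describe replicate 1, the disruptant ratios of dbp3 (AO090001000749) and atfB (AO090120000418) became −0.17 and 0.044. Of 181 called ratios of named genes, 93 moved by over 1.5-fold with scale normalization, 56 with the block, 29 under median centring, 20 with the scanner's log ratios, 27 without overexpressor replicate 3 and 7 without disruptant replicate 1.

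Genes changed in the disruptant numbered 1524 on their own arrays, 0 with the replicate block (limma, 1759 at an unadjusted p under 0.05), 938 at a minimum of 2-fold, and 1476 to 3124 with 1 array left out (1476 without disruptant replicate 2, 1825 without 3, 1925 without 4). Genes changed in the overexpressor numbered 7290 on their own arrays, 2199 with the block, 4411 with scale normalization, 3758 at 2-fold, and 5293 to 6956 with 1 array left out. The difference passed for 2619 genes with the block, 890 with scale normalization, 2466 at 2-fold, and 1786 to 4366 with 1 array left out (1786 without overexpressor replicate 1, 1989 without 2). Genes lower in the disruptant and higher in the overexpressor numbered 35 on their own arrays, 0 with the block, 15 at 2-fold, and 29 to 53 with 1 array left out (45, 29 and 44 without disruptant replicates 1, 2 and 4, and 39, 39 and 45 without overexpressor replicates 1, 2 and 3). The 2-fold minimum removes genes by construction. For the other settings the cause was not tested.

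Planned lists that passed in the disruptant numbered 2 with the scanner's log ratio, 2 with the series table, 0 with median centring, 0 with an estimated correlation and 2 with fry, and with 1 array left out 1 at both ends. In the overexpressor they numbered 2 with fry, and 0 to 1 with 1 array left out (1 without overexpressor replicate 3). Added lists in the disruptant numbered 5 on own arrays, 1 with the block, 0 with an estimated correlation, and 2 to 7 with 1 array left out (7 without disruptant replicate 1, 6 without 4, 5 without overexpressor replicate 3). In the overexpressor they numbered 3 with the block, 0 with an estimated correlation, 9 with fry, and 4 to 6 with 1 array left out. The cause was not tested.

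The labels do not say whether replicate numbers pair the arrays. Residuals of arrays with the same number correlated at 0.386, −0.135 and −0.107 across genes. Residuals of a single fit offset each other, so these values do not settle the pairing. The replicate block is therefore no established paired analysis. Its mutant terms describe the change at replicate 1, which stood apart in the disruptant, and few degrees of freedom are left. Its lower counts are therefore not read as smaller effects. Its count of 0 genes in the disruptant does not measure the mean change over the disruptant arrays. A median or a brightest value over several probes was not run, since 12106 of 12107 genes have 1 probe. Low signal limits the genes with a channel near background, and no ratio is given for a named gene in a strain whose channel was well above background on 0 arrays.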

Other observations

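The tests in this part were chosen only after the results were seen, and the genes named here were chosen after their values were seen. Neighbouring genes moved together in several places. In windows of 10 neighbouring tested genes in the RefSeq order, the largest mean rise in the overexpressor, 2.28 on the log2 scale, lay in a run of 18 genes that holds mirB, a siderophore transporter gene. Of this run 13 genes rose and 1 fell in the overexpressor (permutation p = 0.001 from 1000 shuffles of gene positions, the smallest they can give). A run of 13 genes that holds niiA, the nitrite reductase gene, had 7 rising genes in the disruptant and 7 rising and 1 falling in the overexpressor (highest mean 1.27 in the disruptant, permutation p = 0.001). The run of 10 genes from AO090038000445 and manF to AO090038000432 and with cbhC had 4 falling in the disruptant and 6 rising and 3 falling in the overexpressor (mean difference 1.57, permutation p = 0.027). A run of 10 genes from AO090023000001 to AO090023000015 had 8 falling in each mutant, with means of −1.23 in the disruptant (permutation p = 0.006) and −2.47 in the overexpressor (permutation p = 0.004).

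pmi1, AO090012000554, the mannose phosphate isomerase gene that links mannose to glycolysis, rose by log2 1.75 ± 0.21 in the overexpressor (SE, n = 3, limma adjusted p = 0.000644) and had −0.56 ± 0.18 in the disruptant (n = 4, adjusted p = 0.0566). The difference was 2.31 ± 0.28 (adjusted p = 0.00278). AO090011000869, next to pyrG in the RefSeq order, fell by 2.88 ± 0.20 in the disruptant and by 3.09 ± 0.24 in the overexpressor, while pyrG, AO090011000868, had 0.97 ± 0.14 and 0.06 ± 0.17. Of the 27 loci of the aflatoxin cluster, deleted per the labels, 23 had a mean log2 intensity under 7, and the other 4 were AO090026000004, AO090026000005, AO090026000008 and AO090026000023.

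The run around gliP was tested against a chance placement of single genes. Its lowest mean difference over 10 neighbouring genes, overexpressor minus disruptant, was −3.63, and a chance placement is excluded (permutation p = 0.001, the smallest possible from 1000 shuffles). A joint control of the run by manR or by something that differs along with it may be considered, and no biological explanation was tested.

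A probe for manR might be present under another name. AO090011000944 had a log2 ratio of −0.707 in the overexpressor, where a raised manR would give a rise if the probe lies in the overexpressed part. The position of the probe in the gene is not given, so this ratio does not settle whether the locus is manR. AB701764, which fell by 2.83 and rose by 2.22, cannot be told apart from a gene that follows manR, since it was well above background on 4 disruptant arrays. Among genes well above background in the control channel of at least 3 disruptant arrays and in the disruptant channel of 0, 6 rose in the overexpressor, with AO090005001553 at 3.81 ± 0.23 and AO090102000262 at 3.72 ± 0.18 the highest. Of the 6, only AO090005001553 was also called lower in the disruptant (limma adjusted p = 0.0178, against 0.204 for AO090102000262). For the others the absence rests on the background flag alone. No further test of these was possible without an annotation of the disrupted locus.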
